A study of Bos taurus with 24 samples.

How the data were processed

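RNA sequencing measured RNA levels in bovine muscle satellite cells, the stem cells of skeletal muscle, taken from the longissimus dorsi muscle. Per the labels, a mix of 3 satellite cell lines at passage 3 and fibroblasts at passage 10 were plated at 8000 cells/cm2 in 6-well plates and co-culture plates with 0.4 µm pores, in medium with 20% fetal bovine serum. After 5 days the medium was changed to one with 10% horse serum, which starts differentiation. The 24 libraries fall into 6 groups of 4 by the titles: monoculture and coculture, each in proliferation, 24 h and 72 h after the change of medium. The labels do not say whether monoculture wells held an empty insert, and they do not say that replicates come from separate cultures. Libraries were made from 400 ng of total RNA with the Vazyme VAHTS Universal V8 kit.

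The authors deposited a table of gene counts, a whole number of reads per gene and library (counts); FastQC, STAR, RSEM and DESeq2 are named in the submitters' processing notes, without versions. The counts may be rounded RSEM estimates, and the genome build is not given in the sources used here. Per the file headers, 3 further deposited tables, 1 per time, hold the log2 fold change of coculture over monoculture with its standard error, on the log2 scale, and the p-values, unadjusted and adjusted, of the authors' model. These tables were read only for the comparison named as such. The count table has 36 library columns, of which 24 carry the library names in the labels. The other 12 columns match no label and were not used in any step.

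The table lists 11937 genes with Ensembl identifiers and coordinates, 11480 of them protein coding and 423 lncRNA; 893 have no symbol and 140 symbols are shared by more than 1 gene. Every listed gene has at least 6 counts in every library used, so genes silent in any of them are not among the genes listed. The gene lists described below hold 817 distinct symbols, of which 585 are listed. Library totals run from 11.5 to 34.96 M counts. The biological coefficient of variation fitted by edgeR was 6.86%, from a common dispersion of 0.0047.

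Counts were analysed in R 4.3.3 with edgeR 4.0.16. Scaling factors came from the TMM method. The filterByExpr rule removed 0 genes. A single model with 1 mean per group was fitted to all 24 libraries, which leaves 18 residual degrees of freedom, and each comparison was tested with edgeR's quasi-likelihood F test. The p-values were adjusted by the Benjamini-Hochberg method over the 11937 genes, and a gene is called at an adjusted p under 0.05. Fold changes are log2 values with standard errors (SE). The SE is the size of the log2 fold change over the square root of the F statistic. It uses 1 spread per gene for all 6 groups, so it does not follow a group that varies more than the others. Levels are counts scaled to the same library total with the TMM factors (CPM), as mean and SD over 4 libraries.

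The comparisons, the tests, the gene lists and the naming rule were fixed before the data were examined. There are 10 comparisons: coculture against monoculture at each of 3 times, the change of that difference between each pair of times, and the change over time within each culture. For each coculture against monoculture comparison the rule names the 10 genes with the largest rise and the 10 with the largest fall among called genes that have a symbol, a mean of at least 5 CPM in the higher group, and no overlap between the 4 libraries of one group and the 4 of the other. For the other comparisons it names 5 in each direction, without the overlap condition for changes of the difference, where the highest of the 4 groups must reach 5 CPM. In addition 11 genes were to be named whatever they did: PAX7, MYF5, MYOD1, MYOG, MYMK, MYH3, MKI67, PDGFRA, COL1A1, MSTN and IGF2. Members of a list are given as examples when they moved most among those called, except that 2 genes are not reported here.

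The 27 gene lists cover satellite cell identity and quiescence, myogenic regulators, sarcomere and contractile apparatus, myoblast fusion, excitation-contraction and neuromuscular junction, cell cycle, extracellular matrix components, matrix remodelling enzymes and inhibitors, growth factors and their binding proteins, TGF-beta and BMP responsive genes, the Notch pathway, cytokines, chemokines and NF-kB targets, interferon response, hypoxia and glycolysis, oxidative phosphorylation, cholesterol biosynthesis, amino acid and ER stress response, and atrophy and protein breakdown. They also cover markers of fibroblasts and fibro-adipogenic progenitors, adipocytes, smooth muscle and pericytes, endothelium, leukocytes, and bone and cartilage cells, and lists that move with RNA handling: immediate early and heat shock genes, mitochondrially encoded genes and cytosolic ribosomal proteins. Each list with at least 3 members listed was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The same test was repeated with a correlation estimated from the data. Camera compares a list with the other genes. The number of members called is given over all genes and, where it differs, adjusted over the list alone.

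The procedure was tested on simulated data with the dispersion of this series, 11937 genes, and 100 genes changed 1.25-fold and 100 changed 1.5-fold in each comparison simulated. For coculture against monoculture, 53%, 49% and 62% of the 1.25-fold changes and 87%, 93% and 85% of the 1.5-fold changes were recovered in proliferation, at 24 h and at 72 h. For the change of the difference between 24 h and 72 h, 18% and 67% were recovered. A set of 40 genes that was shifted together was called, and 0 of 20 sets of unchanged genes were. Genes were simulated independently of each other, so this does not show how often camera falsely calls lists of correlated genes. Each gene had 1 spread for all groups. Only 200 genes were changed, far fewer than were called in the data, so the shares recovered need not hold there.

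The libraries of the series come from 2 sequencing lanes, each with its own library pool. All monoculture libraries, the coculture proliferation libraries and coculture 24 h replicates 1 and 2 lie in lane 6. Coculture 24 h replicates 3 and 4 and all coculture 72 h libraries lie in lane 7. The labels also carry a code with no stated meaning, which is 1 for monoculture at 24 h and 72 h and 2 for all other libraries. The difference between cultures at 72 h is therefore confounded with the lane, and at 24 h and 72 h with the code. The change in monoculture from proliferation to 24 h and the changes of the difference from proliferation are confounded with the code too. At 24 h the difference, and both changes over time in coculture, are confounded with the lane in part.

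The alternatives fixed in advance were size factors by relative log expression, library sizes without factors, other filters on low counts, DESeq2 1.42.0, limma voom, a fit to only the libraries compared, the sample number as a block, the lane as a covariate, lane 6 alone, each library left out in turn, an adjusted p under 0.01, and a change of at least 2-fold. For the gene lists they were the sample number as a block and the estimated correlation. Leaving out the 4 libraries above 1.5% nuclear ribosomal RNA, leaving out the 2 nuclear ribosomal RNA genes, and all alternatives for the correlation between the effects at different times were chosen after seeing the data. The sample numbers in the titles were not used to pair libraries.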

Results

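The series asks how fibroblasts, acting through shared medium, change dividing and differentiating bovine satellite cells. RNA from satellite cells grown alone (monoculture) or across a 0.4 µm pore membrane from fibroblasts (coculture) was sequenced in proliferation, at 24 h and at 72 h after the change to horse serum medium, with 4 libraries in each of the 6 groups. Library totals were 14.5 to 18.2, 16.2 to 23.9 and 14.97 to 22.6 M counts in monoculture, in order of time. In coculture they were 11.5 to 34.96, 16.8 to 22.2 and 17.3 to 21.4 M. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

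The first principal component of log2 CPM held 48.5% of the variance and the second 17.1%. Mitochondrial protein-coding transcripts took 2.05% ± 0.0502, 3.03% ± 0.218 and 2.37% ± 0.167 of counts in monoculture (SD, n = 4), and 1.65% ± 0.0409, 2.24% ± 0.113 and 1.84% ± 0.0729 in coculture. Nuclear ribosomal RNA took 1.23 to 1.40% of counts in monoculture and 0.742 to 1.07% in coculture in proliferation. Later it was at most 0.934% in all but 4 libraries: coculture 24 h replicate 2 (4.07%), coculture 72 h replicate 1 (2.24%) and monoculture 72 h replicates 3 (2.14%) and 4 (1.76%).

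**Figure D1:**
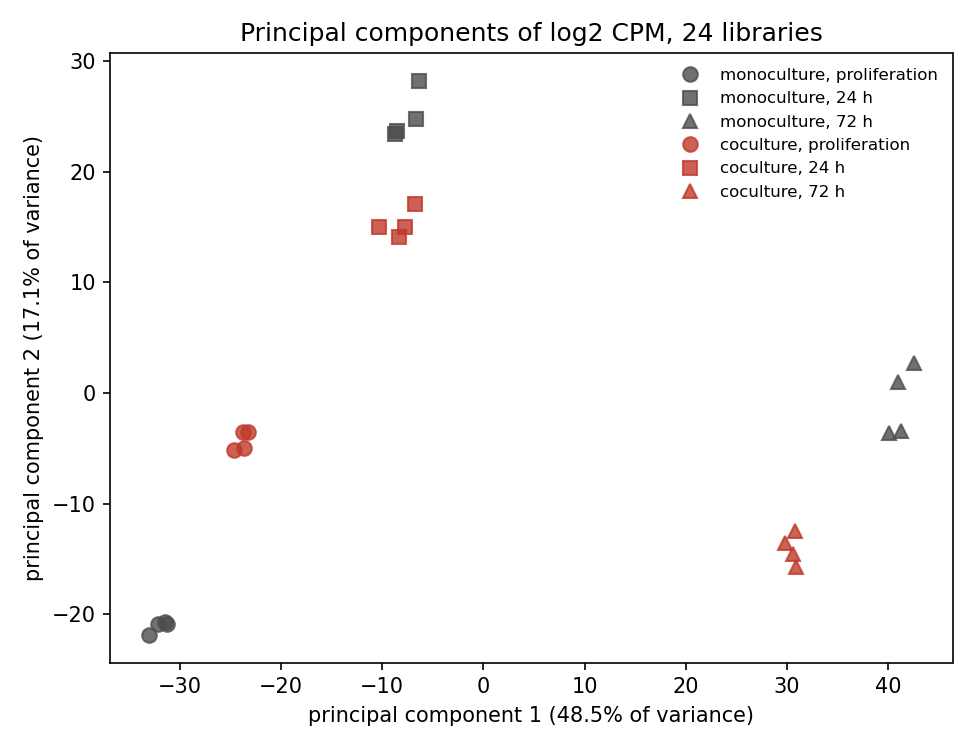
Principal components 1 and 2 of log2 CPM over 11937 genes, 1 point per library, with 48.5% and 17.1% of the variance; colour gives the culture and shape the time. The 4 libraries of each group lie together, and monoculture and coculture lie apart at each time.

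In proliferating cells, coculture lowered the genes of cholesterol synthesis. HMGCS1, which makes HMG-CoA for the mevalonate pathway, was at 58.8 ± 1.17 CPM in coculture and 160 ± 10.5 in monoculture (SD, n = 4), a log2 fold change of -1.44 ± 0.0507 (SE; edgeR adjusted p = 2.92e-19). SQLE, the squalene epoxidase of the same pathway, fell by 1.36 ± 0.0596 on the log2 scale. SPP1, which encodes the secreted phosphoprotein osteopontin, stood at 249 ± 6.44 against 613 ± 27.9 CPM (log2 -1.30 ± 0.0537, adjusted p = 1.53e-17). MX1, an interferon-induced GTPase with antiviral activity, rose from 2.29 ± 0.395 to 12.1 ± 0.726 CPM (log2 2.41 ± 0.257, adjusted p = 4.48e-09). The table places HMGCS1 (ENSBTAG00000011839) on chromosome 20 at 31431059 to 31456871 and SPP1 (ENSBTAG00000005260) on chromosome 6 at 36693206 to 36700390. MX1 (ENSBTAG00000030913) lies on chromosome 1 at 141677698 to 141706496, on a build not given in the sources used here.

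Among the other largest rises were IFITM3 (log2 1.65), an interferon-induced membrane protein whose symbol is shared by more than 1 gene, the matrix protease ADAMTS9 (1.47), the RNA sensor DHX58 (1.39), the phosphodiesterase PDE1B (1.29), the DNA polymerase POLM (2.38-fold), the lipase inhibitor ANGPTL4 (1.13), the cytokine signalling inhibitor SOCS3 (1.10), ERP27 (1.09) and APOA1 (1.07). Further large falls were GCA (-1.83), the small leucine-rich proteoglycan ASPN (-1.58), CCNG2 (-1.49), the laminin chain LAMA3 (-1.41), the retinoic acid hydroxylase CYP26B1 (-1.40), NTS (-1.38) and the fatty acid desaturase SCD (-1.62). The naming rule takes only genes in which the 4 libraries of one culture lie above the 4 of the other, which holds for each gene it named at any time. MKI67, a marker of dividing cells, rose by a log2 of 0.34 ± 0.0791 (adjusted p = 0.00047).

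Of 24 measured cholesterol biosynthesis genes, 19 fell and none rose (camera adjusted p = 5.84e-08, and adjusted p = 0.000392 with an estimated correlation). MSMO1 (-1.16 ± 0.0583), a sterol methyl oxidase, followed HMGCS1 and SQLE. Interferon response genes rose in 13 of 29 cases and fell in 3 (11 and 5 with library sizes alone), but were not called as a list (adjusted p = 0.108). The amino acid and ER stress response list had 19 of 32 genes higher, led by SDF2L1 (0.70), TRIB3 (0.66) and SESN2 (0.63), and 3 lower, among them DNAJB9 (-0.35; 16 and 5 with library sizes alone; adjusted p = 7e-04, and adjusted p = 0.0124 with an estimated correlation). Glycolysis and hypoxia genes rose in 18 of 31 cases, as the lactate exporter SLC16A3 (1.88 ± 0.293), TPI1 (0.72) and ALDOA (0.71), and fell in 5, as MXI1 (-0.82; adjusted p = 7e-04, but adjusted p = 0.655 with an estimated correlation). Matrix remodelling enzymes rose in 24 of 33 cases, with the urokinase receptor PLAUR at 0.94 ± 0.0514, and fell in 7, with ADAMTS5 at -0.77 (adjusted p = 0.00119, but adjusted p = 0.0876 with an estimated correlation).

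Matrix components themselves rose in 25 of 47 cases and fell in 4 (20 and 10 with library sizes alone). COL18A1 (0.69), COL6A3 (0.69) and COL1A1 (0.50 ± 0.0389) rose, TNXB (-1.11) and LUM (-0.44) fell (adjusted p = 0.00476, but adjusted p = 0.66 with an estimated correlation). Cell cycle genes rose in 21 of 40 cases, with the replication licensing factors MCM5 (0.88), MCM3 (0.76) and MCM2 (0.70), and fell in 5, with HMMR (-0.36; adjusted p = 0.00911, but adjusted p = 0.66 with an estimated correlation). TGF-beta and BMP responsive genes rose in 10 of 22 cases, ID1 (1.06) and TGFBI (0.99) most, and SKIL fell (-0.49; 4 fell with library sizes alone; adjusted p = 0.0151, but adjusted p = 0.109 with an estimated correlation). Oxidative phosphorylation genes in the nucleus rose in 26 of 55 cases, as NDUFS7 (0.63) and CYC1 (0.61), and fell in 8, or 9 adjusted over the list alone and 13 with library sizes alone (adjusted p = 0.00732, but adjusted p = 0.66 with an estimated correlation). In contrast 10 of 13 mitochondrially encoded genes fell and none rose, ATP8 (-0.92) and COX2 (-0.50) most (adjusted p = 0.00119, but adjusted p = 0.66 with an estimated correlation). Of 13 smooth muscle and pericyte markers 10 rose, DES (0.80) and SMTN (0.58) most, and 3 fell, with MCAM at -0.46 (adjusted p = 0.00732, but adjusted p = 0.362 with an estimated correlation). Counts adjusted over the list alone equal those given unless stated.

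In total edgeR's quasi-likelihood test called 7041 of 11937 genes in proliferation, 3613 higher and 3428 lower in coculture, of which 29 and 48 changed at least 2-fold. The median size of a called change was a log2 of 0.34. Of the called genes 51.3% were higher, against 39.5% with library sizes alone. The proliferation libraries all come from lane 6 and carry the same label code, and those of coculture held less nuclear ribosomal and mitochondrial RNA.

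At 24 h of differentiation, the largest rise was in EGR1, a transcription factor induced within minutes of growth factor signalling: 30.4 ± 4.82 CPM in coculture against 2.69 ± 0.755 in monoculture (log2 3.47 ± 0.132, adjusted p = 1.53e-18). The related early gene NR4A1 rose by 1.40 ± 0.099. Of the 24 immediate early and heat shock genes 7 rose and 7 fell (7 and 8 adjusted over the list alone, 6 and 4 within lane 6 alone; median -0.06, mean 0.14; camera adjusted p = 0.88). FGF7, a growth factor that mesenchymal cells secrete, rose from 8.31 ± 0.795 to 24.5 ± 3.61 CPM (1.56 ± 0.111). SPP1 was lower again, at 206 ± 10.4 against 744 ± 34.7 CPM (-1.85 ± 0.0545, adjusted p = 1.66e-21). ITGA7, the laminin receptor subunit of muscle cells, stood at 57.9 ± 4.53 against 131 ± 8.57 CPM (-1.17 ± 0.0808). EGR1 (ENSBTAG00000010069) lies on chromosome 7 at 49826480 to 49830253.

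The cyclic AMP phosphodiesterase PDE4B (log2 3.16), MX1 (2.52 ± 0.263), CCDC3 (2.31), ADAMTS9 (1.75), IFITM3 (1.45), the cholesterol hydroxylase CH25H (1.27) and TSHZ2 (1.22) also rose. CYP26B1 (-1.46), the matrix glycoprotein TNXB (-1.38), the histone deacetylase HDAC9 (-1.33), FAM180A (-1.27), MAMDC2 (-1.20), the adhesion molecule ICAM1 (-1.19), the extracellular chaperone CLU (-1.18) and CRTAC1 (-1.08) fell. MKI67 was at 133 ± 13.8 CPM in coculture and 136 ± 12.1 in monoculture (adjusted p = 0.8).

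Of 6 lists called by camera at 24 h, none kept its call with an estimated correlation. Glycolysis and hypoxia genes rose in 22 of 31 cases (23 adjusted over the list alone), with SLC16A3 (2.13 ± 0.282), hexokinase HK2 (0.83) and BNIP3L (0.48), and only ADM fell (-0.38; adjusted p = 9.84e-12, but adjusted p = 0.146 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases (13 adjusted over the list alone), with COX2 (-0.51) and COX3 (-0.49), and none rose (adjusted p = 9.84e-12, but adjusted p = 0.146 with an estimated correlation). Cytosolic ribosomal protein genes rose in 30 of 50 cases (41 adjusted over the list alone, 12 within lane 6 alone) and none fell. The rises were small, such as 0.31 for RPS23 and 0.26 for RPL34 (camera adjusted p = 3.81e-10, but adjusted p = 0.508 with an estimated correlation). That list holds 45 symbols, so some of the 50 genes share a symbol. Interferon response genes rose in 15 of 29 cases, with IFI6 (1.15) and USP18 (0.88) next to MX1, and TAP1 fell (-0.41; 18 and 3 adjusted over the list alone; adjusted p = 0.000362, but adjusted p = 0.508 with an estimated correlation). Of 47 matrix components 5 rose, DCN (0.76) most, and 15 fell, with POSTN at -0.58 and AGRN at -0.45 (5 and 17 adjusted over the list alone, 3 and 11 within lane 6 alone; adjusted p = 0.0237, but adjusted p = 0.615 with an estimated correlation). Among 10 genes of satellite cell identity and quiescence, SDC4 rose (0.26) and 5 fell, ITGA7, the hepatocyte growth factor receptor MET (-0.54), CD82 (-0.44) and FGFR1 (-0.40) among them (2 and 5 adjusted over the list alone; adjusted p = 0.0258, but adjusted p = 0.146 with an estimated correlation).

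The 24 h comparison called 2836 genes, 1376 higher and 1460 lower, of which 26 and 32 changed at least 2-fold. Within lane 6 alone, with 2 coculture libraries, 1746 genes were called (804 higher, 942 lower), 1663 of them among the 2836. Of these 2 libraries, replicate 2 held 4.07% nuclear ribosomal RNA. The label code is confounded with the culture at 24 h and at 72 h.

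By 72 h the cells in coculture held more transcripts of interferon response and cell cycle genes and fewer of the 12 sarcomere genes measured, out of 53 on that list. MX1 reached 52.7 ± 8.84 CPM against 3.17 ± 0.416 (log2 4.06 ± 0.214, adjusted p = 1.05e-15). IL6, a cytokine of inflammation, stood at 128 ± 59.3 against 20.2 ± 5.87 CPM (2.67 ± 0.215), and the chemokine CXCL5 at 479 ± 159 against 82.3 ± 20.0 (2.54 ± 0.164). MKI67 was at 54.8 ± 3.6 against 21.4 ± 3.39 CPM (1.35 ± 0.0918, adjusted p = 3.04e-13). ITGA7 fell to 38.5 ± 7.05 against 155 ± 7.2 CPM (log2 -2.02 ± 0.0839) and SPP1 to 129 ± 12.7 against 509 ± 19.7 (-1.98 ± 0.0551).

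Further rises were PDE4B (log2 3.31), CCDC3 (2.89), ADAMTS9 (2.80), the mitochondrial superoxide dismutase SOD2 (2.75), IFITM3 (2.70), SLC16A3 (2.53) and DHX58 (2.47). Further falls were HDAC9 (-2.78), the hexokinase HK3 (-2.53), the ERK phosphatase DUSP5 (-2.53), ALKAL1 (-2.38), the water channel AQP1 (-2.25), TNXB (-2.06), LGI2 (-2.05) and the taurine transporter SLC6A6 (-1.79). Without the 4 libraries rich in nuclear ribosomal RNA, the value for PDE4B was 4.12. PDGFRA, a receptor of fibro-adipogenic progenitors, rose to 121 ± 12.1 against 46.3 ± 3.24 CPM (1.38 ± 0.0582). COL1A1, the main fibrillar collagen gene, was slightly lower (-0.21 ± 0.0388, adjusted p = 3.63e-05). It alone took 5.21% ± 0.0243 of counts in coculture and 5.51% ± 0.170 in monoculture at 72 h (SD, n = 4).

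**Figure D2:**
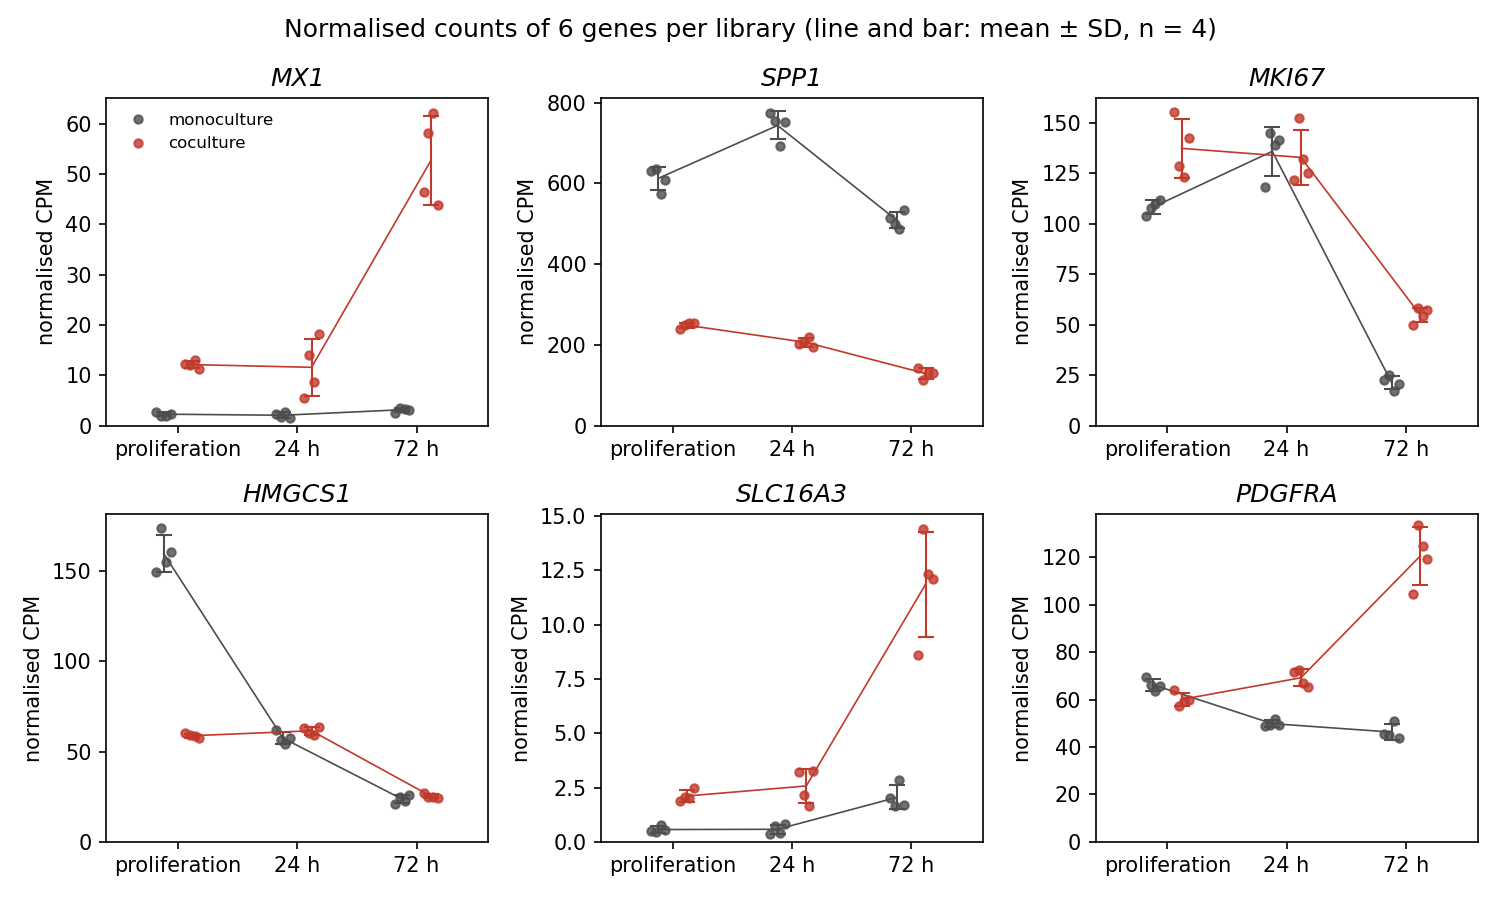
Normalised counts (CPM) of 6 genes, 1 point per library at 3 times; lines join the group means and bars show SD (n = 4). At 72 h MX1 lies between 43.9 and 62.1 CPM in coculture and 2.61 and 3.61 in monoculture, and MKI67 fell from 24 h to 72 h in both cultures.

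All 40 cell cycle genes rose, with TOP2A (1.63 ± 0.081), RRM2 (1.39), KIF20A (1.38) and CENPE (1.36) highest and a median of 0.97 (adjusted p = 1.29e-24, and adjusted p = 0.0399 with an estimated correlation). Interferon response genes rose in 28 of 29 cases, with DHX58, the RNA sensor IFIH1 (2.40) and XAF1 (2.32) after MX1, and a median of 1.03 (adjusted p = 4.62e-17, and adjusted p = 0.0399 with an estimated correlation). Of the 12 sarcomere genes measured, 7 fell, the M-band protein MYOM1 (-1.92 ± 0.181), XIRP1 (-1.57) and MYL4 (-1.17) most, and TPM3 rose (0.23; adjusted p = 0.0062, and adjusted p = 0.0399 with an estimated correlation). These are the 3 lists that kept the call.

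Cytokines and NF-kB targets rose in 17 of 27 cases, SOD2, IL6, the complement factor CFB (2.64) and CXCL5 most, and IL1RN fell (-1.19; 17 and 2 adjusted over the list alone; adjusted p = 9.36e-05, but adjusted p = 0.183 with an estimated correlation). Glycolysis and hypoxia genes rose in 22 of 31 cases (23 adjusted over the list alone), with SLC16A3 and HK2 (1.26) most, and PFKFB3 fell (-0.51; adjusted p = 3.43e-09, but adjusted p = 0.107 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases (13 adjusted over the list alone), with COX2 (-0.64) and COX1 (-0.58), and in 7 with the lane covariate (adjusted p = 5.78e-06, but adjusted p = 0.183 with an estimated correlation). Matrix remodelling enzymes parted, with 9 of 33 higher, ADAMTS9 and ADAMTS5 (1.61) most, and 20 lower, ADAMTS14 (-1.64), ADAMTS1 (-1.41) and LOXL4 (-1.34) most (10 and 21 adjusted over the list alone; adjusted p = 0.00448, but adjusted p = 0.0977 with an estimated correlation). Growth factors rose in 10 of 40 cases, FGF7 (2.04) and HGF (0.84) most, and fell in 22, as WNT9A (-1.57), IGFBP3 (-1.32) and GDF15 (-1.21; with library sizes alone 14 rose and 14 fell, and with the lane covariate 2 and 17; adjusted p = 0.00881, but adjusted p = 0.0706 with an estimated correlation).

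Smooth muscle and pericyte markers fell in 9 of 13 cases, with CSPG4 (-1.30), MCAM (-0.91) and DES (-0.78), while SMTN (0.42) and ACTG2 (0.28) rose (adjusted p = 0.0023, but adjusted p = 0.109 with an estimated correlation). Immediate early and heat shock genes fell in 13 of 24 cases (14 adjusted over the list alone), with CRYAB (-1.66) and NR4A1 (-1.13), and rose in 5, EGR1 (0.62) most, or in 1 with the lane covariate (adjusted p = 0.00331, but adjusted p = 0.107 with an estimated correlation). TGF-beta and BMP responsive genes fell in 12 of 22 cases, SMAD7 (-0.95) among them, and rose in 4, with the receptor TGFBR1 at 1.14, or 11 and 2 with the lane covariate (adjusted p = 0.037, but adjusted p = 0.108 with an estimated correlation). Matrix components fell in 23 of 47 cases, TNXB and LAMA5 (-1.06) most, and rose in 10, THBS2 (1.05) most (25 and 10 adjusted over the list alone; adjusted p = 0.0376, but adjusted p = 0.561 with an estimated correlation); with library sizes alone 16 rose and 16 fell. Oxidative phosphorylation genes in the nucleus fell in 18 of 55 cases, 1 of the 2 genes named COX6B1 (-0.64) and IDH3A (-0.35) most, and rose in 2, but with library sizes alone 10 rose and 3 fell, and with the lane covariate 1 and 8 (17 and 1 adjusted over the list alone; adjusted p = 0.0155, but adjusted p = 0.561 with an estimated correlation).

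In total 6029 genes were called at 72 h, 2995 higher and 3034 lower, of which 200 and 144 changed at least 2-fold. Of the called genes 49.7% were higher, against 75.3% with library sizes alone, where the median over all genes moved by a log2 of 0.13. All coculture 72 h libraries lie in lane 7 and all monoculture libraries in lane 6, so lane and culture are confounded. With the lane as a covariate, which rests on the 4 coculture 24 h libraries, 3402 genes were called, 3313 of them among the 6029. The medians were then 1.07 for cell cycle and 0.94 for interferon genes. Of those 4 libraries, replicate 2 in lane 6 held 4.07% nuclear ribosomal RNA, so the covariate also carries what sets that library apart.

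**Figure D3:**
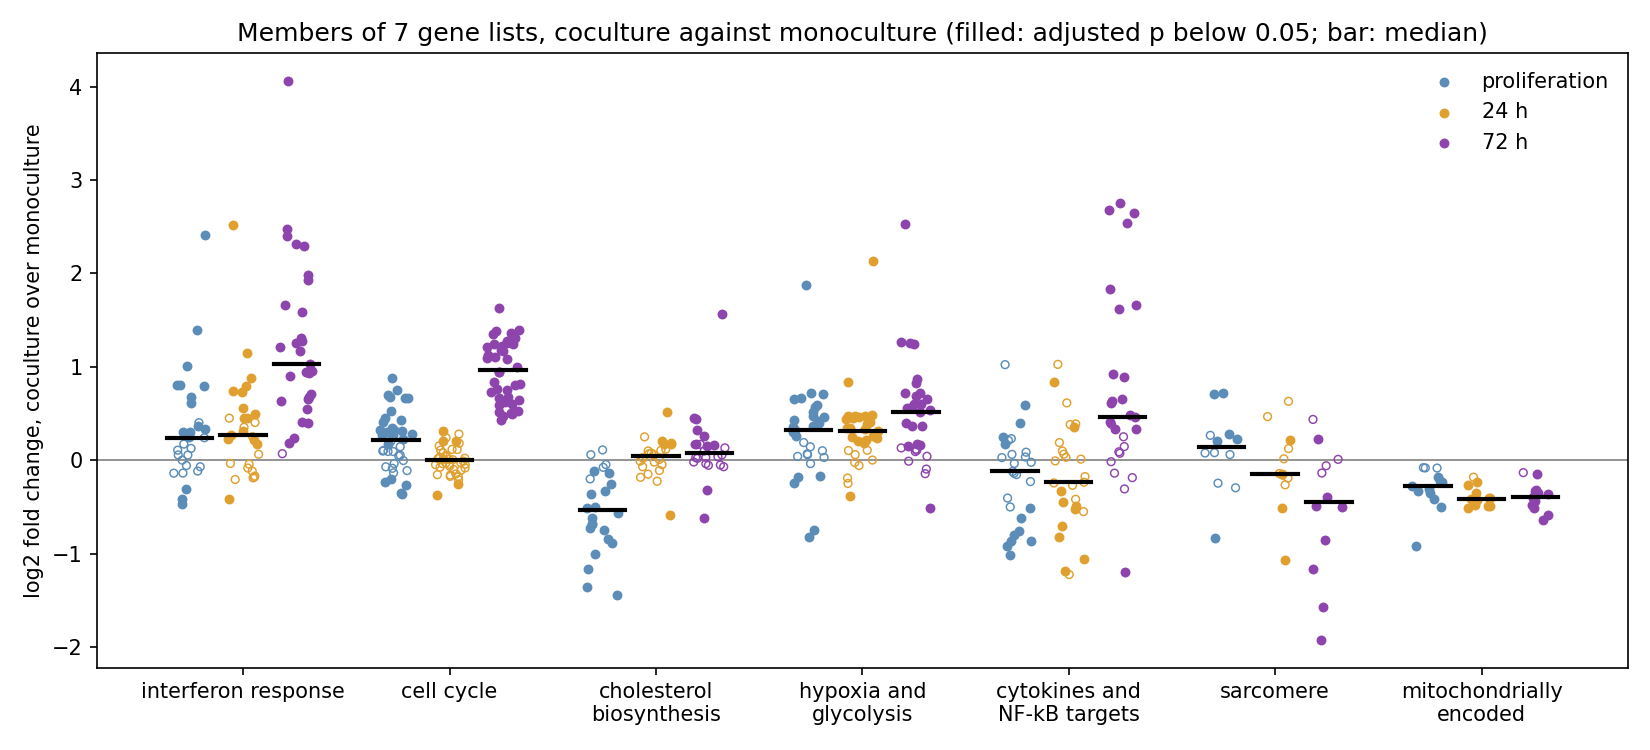
Log2 fold change of coculture over monoculture for the members of 7 gene lists at 3 times, 1 point per gene, filled where called, with a bar at the median. The interferon list median is 1.03 and the cell cycle median 0.97 at 72 h, and the cholesterol median is -0.54 in proliferation.

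Of 13 myogenic regulators measured, 4 rose and 7 fell in proliferation, 3 and 4 at 24 h, and 3 and 5 at 72 h (camera adjusted p = 0.377, 0.711 and 0.407; 4 and 4 at 24 h and 4 and 5 at 72 h adjusted over the list alone). With library sizes alone 6 rose and 5 fell at 72 h, with the lane covariate 1 and 5, and within lane 6 alone 1 and 4 at 24 h. At 72 h the median of this list was 0.04 and its mean -0.24. HDAC9 fell most each time, and TEAD4 (0.50) in proliferation and EYA4 (0.49 and 0.59) at 24 h and 72 h rose most. Of 14 fusion genes 6 rose and 5 fell in proliferation (4 and 5 with library sizes alone). At 24 h 4 rose and 5 fell (4 and 6 adjusted over the list alone, 2 and 2 within lane 6 alone). At 72 h 6 rose and 4 fell (7 and 2 with library sizes alone, 4 and 2 with the lane covariate), and the interleukin receptor IL4R (1.14) and the membrane repair protein MYOF (-0.68) moved most (adjusted p = 0.868, 0.862 and 0.448). Of 9 genes of excitation-contraction coupling 2 rose and 2 fell in proliferation (1 and 2 adjusted over the list alone, 0 and 2 with library sizes alone). At 24 h 0 rose and 1 fell, and at 72 h 1 and 3, where the median is negative but turns positive with library sizes alone. CASQ2, the calsequestrin of the calcium store, fell at each time (-1.11, -0.68 and -1.69; list adjusted p = 0.938, 0.711 and 0.295). The sarcomere list had 5 of 12 higher and 1 lower in proliferation, or 4 and 2 with library sizes alone. At 24 h 1 sarcomere gene rose and 3 fell (camera adjusted p = 0.553 in proliferation and 0.552 at 24 h). Satellite cell identity genes had 3 of 10 higher and 2 lower in proliferation and 3 and 5 at 72 h (adjusted p = 0.653 and 0.133). With library sizes alone these were 2 and 3 and then 3 and 3. At 72 h they were 0 and 3 with the lane covariate, and 1 and 3 without the 4 libraries rich in nuclear ribosomal RNA. PAX7, MYF5, MYOD1, MYOG, MYMK, MYH3, MSTN and IGF2 are not among the genes listed in the table. Every listed gene has at least 6 counts in every library used, so absent genes may have been low in some libraries. The table thus gives no values for the core of the myogenic programme, and in which libraries these genes were low, if any, cannot be told.

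The effect of coculture differed between the times. Between proliferation and 24 h the effect rose most for EGR1 (log2 change of the effect 2.42 ± 0.223, adjusted p = 1.53e-09), PDE4B (1.70), ASPN (1.59), HMGCS1 (1.54 ± 0.0725) and SCD (1.52). It fell most for the transcription factor ETV4 (-1.62), FLVCR2 (-1.44), ERP27 (-1.42), IGSF9 (-1.40) and NUAK2 (-1.35). HMGCS1 no longer differed by the test at 24 h, with 61.5 ± 2.26 CPM in coculture and 57.5 ± 3.25 in monoculture. Across the cholesterol list the effect rose for 18 of 24 genes and fell for 1 (adjusted p = 4.73e-08, and adjusted p = 0.000366 with an estimated correlation). It fell for 30 of 47 matrix components and rose for 4 (adjusted p = 0.000206, but adjusted p = 0.405 with an estimated correlation). The test called 6026 genes, 2896 with a rising and 3130 with a falling effect, and 48.1% were rising, against 58.8% with library sizes alone. This change is confounded with the label code and in part with the lane, and within lane 6 alone 5271 genes were called.

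From 24 h to 72 h the effect rose for RND1 (2.50), SOD2 (2.36), the NF-kB inhibitor TNFAIP3 (2.16), CXCL5 (2.16) and IFIH1 (2.05), and fell for DUSP5 (-3.36), EGR1 (-2.85 ± 0.159), NR4A1 (-2.53), XIRP1 (-2.21) and NR4A2 (-1.98). It rose for 39 of 40 cell cycle genes (40 adjusted over the list alone; adjusted p = 1.94e-35, and adjusted p = 0.0226 with an estimated correlation). The same held for 28 of 29 interferon genes (29 adjusted over the list alone; adjusted p = 1.59e-18, and adjusted p = 0.0315 with an estimated correlation) and 20 of 27 cytokine genes (22 adjusted over the list alone; adjusted p = 6.67e-11, and adjusted p = 0.0411 with an estimated correlation), and fell for none of these. It fell for 10 of 13 smooth muscle markers and rose for SMTN (0.43; 10 and 2 adjusted over the list alone; adjusted p = 3.67e-05). It fell for 12 of 24 immediate early and heat shock genes and rose for 3 (12 and 4 adjusted over the list alone; adjusted p = 0.000171), and fell for 6 of 12 sarcomere genes (adjusted p = 0.00678). Each of these 3 lists had adjusted p = 0.0411 with an estimated correlation. The test called 2826 genes, 1431 rising and 1395 falling; 50.6% were rising, against 85.4% with library sizes alone, a median shift of 0.14.

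Over the whole span from proliferation to 72 h the largest changes of the effect were CXCL5 (3.56), SOD2 (2.98), ADAMTS5 (2.38), IFIH1 (2.27) and SCD (2.23) upward, and DUSP5 (-3.07), HK3 (-2.44), XIRP1 (-2.28), ADAMTS14 (-2.19) and the adenylate cyclase ADCY5 (-2.04) downward. The effect rose for 19 of 24 cholesterol genes and fell for none (camera adjusted p = 5.52e-07, and adjusted p = 0.00127 with an estimated correlation). For matrix remodelling enzymes the effect fell in 23 of 33 cases and rose in 6 (camera adjusted p = 6.5e-05, and adjusted p = 0.0375 with an estimated correlation). The test called 7437 genes, 3740 rising and 3697 falling, 50.3% rising against 71.3% with library sizes alone, a median shift of 0.20. Both changes that end at 72 h carry the confounding with the lane, and this one also that with the label code.

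Across 11937 genes the coculture effects at 24 h and 72 h correlated with Pearson r = 0.50 and Spearman rho = 0.48, and those in proliferation and at 24 h with r = 0.11 and rho = -0.01. Those in proliferation and at 72 h correlated with r = -0.02 and rho = -0.15. Genes are not independent replicates, and the 3 effects share no library. The label code, however, parts the cultures alike at 24 h and 72 h but not in proliferation. Lane 7 holds coculture libraries of these 2 later times only. Agreement due to the code cannot be told apart from agreement due to coculture. The lane difference within coculture at 24 h, from 2 libraries per lane, correlated with the 72 h effect at r = -0.0055. At 24 h and 72 h together, 876 genes were higher at both times, where 345 would be expected from the counts alone, and 996 lower (371 expected). In proliferation and at 72 h, 1363 genes were higher and then lower (918 expected) and 1164 lower and then higher (860 expected). At all 3 times 241 genes were higher and 245 lower, but no expected count was computed for the 3 times together. Ranked by the smallest of their 3 effects, the first were MX1, SLC16A3, ADAMTS9, PDE4B and IFITM3 above, and CYP26B1, SPP1, MAMDC2, TNXB and the prostaglandin synthase PTGES (-1.19, -1.45 and -1.07) below.

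In monoculture, the first 24 h in horse serum medium raised ANGPTL4 from 7.03 ± 0.353 to 93.5 ± 1.16 CPM (log2 3.74 ± 0.0796, adjusted p = 1.12e-25), together with SLC26A10 (2.83), FNDC1 (2.58), ADCY5 (2.37) and the clock gene PER1 (2.29). SCD (-1.86 ± 0.0979), the interleukin 33 receptor IL1RL1 (-1.66), CARNMT1 (-1.64), PERP (-1.63) and OGN (-1.62) fell. Matrix components rose in 39 of 47 cases (40 adjusted over the list alone), HSPG2 (1.37), FN1 (1.28) and COL1A1 (1.21 ± 0.0394) most, and 4 fell, DCN (-0.87) most (adjusted p = 5.22e-10, but adjusted p = 0.129 with an estimated correlation). Cholesterol genes fell in 19 of 24 cases, HMGCS1 (-1.48) most, and rose in 2 (adjusted p = 5.11e-05, and adjusted p = 0.00945 with an estimated correlation). Ribosomal protein genes fell in 44 of 50 cases and rose in none (adjusted p = 1.56e-07, but adjusted p = 0.487 with an estimated correlation). The comparison called 8179 genes, 4092 higher and 4087 lower; 50.0% were higher, against 29.5% with library sizes alone, a median shift of -0.19. The label code differs between these 2 groups and cannot be told apart from the time.

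From 24 h to 72 h in monoculture all 40 cell cycle genes fell, at a median of -2.01 (adjusted p = 2.68e-34, and adjusted p = 0.0131 with an estimated correlation). MKI67 fell by 2.66 ± 0.0903 on the log2 scale, and the mitotic genes HJURP (-2.90), KIF20A (-2.84), ERCC6L (-2.82), CCNF (-2.80) and SHCBP1 (-2.74) fell most. EGR1 rose from 2.69 ± 0.755 to 203 ± 25.4 CPM (6.20 ± 0.121, adjusted p = 2.88e-27), with the carbonic anhydrase CA13 (5.35), NR4A1 (5.20), the potassium channel subunit KCNE4 (5.18) and TSPAN13 (4.89). Immediate early and heat shock genes rose in 15 of 24 cases (16 adjusted over the list alone), FOS (4.01) next to EGR1 and NR4A1, and fell in 5 (adjusted p = 0.000113, and adjusted p = 0.0469 with an estimated correlation). Cholesterol genes fell in 20 of 24 cases, SQLE (-1.48) most, and none rose (adjusted p = 1.86e-12, and adjusted p = 2.53e-05 with an estimated correlation). Matrix remodelling enzymes rose in 21 of 33 cases, LOXL4 (1.52) most, and fell in 7, or 8 adjusted over the list alone (adjusted p = 0.000162, and adjusted p = 0.0355 with an estimated correlation). The comparison called 6430 genes, 3255 higher and 3175 lower; 50.6% were higher, against 27.0% with library sizes alone, a median shift of -0.13.

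In coculture, ANGPTL4 rose over the first 24 h from 15.3 ± 1.6 to 109 ± 5.02 CPM (log2 2.83 ± 0.0716, adjusted p = 1.91e-23), as did the collagen hydroxylase P4HA3 (2.57), EGR1 (2.24), PER1 (2.19) and the insulin receptor substrate IRS2 (1.97). IL1RL1 (-2.60), FLVCR2 (-2.45), the hyaluronan-degrading CEMIP (-2.29), ID1 (-2.20) and RENBP (-2.15) fell. Matrix components rose in 30 of 47 cases, HSPG2 (0.97) and FN1 (0.91) most, and fell in 3 (31 and 3 adjusted over the list alone; adjusted p = 3.17e-10, but adjusted p = 0.149 with an estimated correlation). Cell cycle genes fell in 26 of 40 cases, MCM3 (-0.63) and MCM5 (-0.62) most, and rose in 2 (27 and 2 adjusted over the list alone, 14 and 2 within lane 6 alone; adjusted p = 1.81e-05, but adjusted p = 0.354 with an estimated correlation). The comparison called 5159 genes, 2504 higher and 2655 lower; 48.5% were higher, against 21.7% with library sizes alone, a median shift of -0.12. Of the 4 libraries at 24 h 2 lie in lane 7, and within lane 6 alone 3494 genes were called (54.4% higher), or 3814 with the lane covariate.

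Between 24 h and 72 h in coculture, IL6 rose from 3.15 ± 0.399 to 128 ± 59.3 CPM (5.33 ± 0.278, adjusted p = 2.33e-16), with TSPAN13 (5.78), the Wnt antagonist SFRP4 (4.88), CA13 (4.39) and CFB (4.31). HDAC9 (-2.90), SKOR1 (-2.57), the elastin gene ELN (-2.35), AQP1 (-2.34) and ATP6AP1L (-2.09) fell. Cell cycle genes fell here too, 39 of 40 (40 adjusted over the list alone), at a median of -0.92 (adjusted p = 5.87e-23, but adjusted p = 0.0638 with an estimated correlation), and MKI67 fell by 1.28 ± 0.0822. Cholesterol genes fell in 18 of 24 cases and rose in none (adjusted p = 7.72e-12, and adjusted p = 3.61e-05 with an estimated correlation). Interferon response genes rose in 24 of 29 cases (25 adjusted over the list alone), MX1 (2.15) and SAMD9 (1.87) most (adjusted p = 1.34e-09, but adjusted p = 0.122 with an estimated correlation). Cytokine genes rose in 22 of 27 cases and fell in 2 (23 and 2 adjusted over the list alone; adjusted p = 4.75e-08, but adjusted p = 0.122 with an estimated correlation). The comparison called 5756 genes, 2910 higher and 2846 lower, and is confounded in part with the lane.

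The authors' deposited table, at an adjusted p of 0.05, calls 6827, 2526 and 5113 genes in proliferation, at 24 h and at 72 h. Of these, 6658, 2399 and 5096 were also called here, each with the same sign. A further 383, 437 and 933 genes were called here only. Across genes the log2 fold changes in the authors' deposited table and those here correlated with r of at least 0.99968. Both rest on the same libraries, so this was likely from the start. The SE differed more. At 72 h it was 0.417 in the deposited table and 0.215 here for IL6, and 0.35 and 0.169 for HDAC9. For MX1 in proliferation it was 0.151 in the deposited table and 0.257 here.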

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

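The 2 tests of the label code were chosen after the results were seen, and the other tests of this part before. Between proliferation and 24 h the coculture effect changed in 6026 genes, rising for EGR1 (log2 2.42, adjusted p = 1.53e-09), PDE4B (1.70, 0.0063), ASPN (1.59, 3.51e-10), HMGCS1 (1.54, 1.24e-15) and SCD (1.52, 3.51e-09). It fell for ETV4 (-1.62, 2.59e-06), FLVCR2 (-1.44, 1.9e-05), ERP27 (-1.42, 8.76e-06), IGSF9 (-1.40, 4.73e-09) and NUAK2 (-1.35, 5.22e-13). Between proliferation and 72 h it changed in 7437 genes, rising for CXCL5 (3.56, 2.67e-13), SOD2 (2.98, 4.34e-09), ADAMTS5 (2.38, 1.42e-12), IFIH1 (2.27, 3.66e-08) and SCD (2.23, 2.47e-11), and falling for DUSP5 (-3.07, 1.56e-07), HK3 (-2.44, 2.11e-12), XIRP1 (-2.28, 1.08e-07), ADAMTS14 (-2.19, 3.18e-09) and ADCY5 (-2.04, 5.34e-06). Between 24 h and 72 h it changed in 2826 genes, rising for RND1 (2.50, 4.06e-05), SOD2 (2.36, 1.97e-06), TNFAIP3 (2.16, 5.95e-07), CXCL5 (2.16, 1.8e-08) and IFIH1 (2.05, 1.78e-06), and falling for DUSP5 (-3.36, 7.25e-08), EGR1 (-2.85, 7.51e-14), NR4A1 (-2.53, 1.99e-15), XIRP1 (-2.21, 1.1e-05) and NR4A2 (-1.98, 2.88e-11).

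Some libraries stood far from the other 3 of their group by Dixon's test. In coculture in proliferation these were IFITM3 in replicate 3 (19.3 CPM, others 12.55 to 13.2), ADAMTS9 in replicate 4 (7.99, others 5.96 to 6.18) and LAMA3 in replicate 3 (7.92, others 6.11 to 6.26). In monoculture they were CRTAC1 in replicate 3 at 24 h (9.90, others 10.5 to 10.6) and, in replicate 3 at 72 h, HDAC9 (25.4, others 15.7 to 16.4) and LGI2 (168, others 98.4 to 105). Chance gives about 1 in 20 groups, so 6 of the 120 groups tested for named genes, and 6 passed. Of 18 groups tested for library measures 3 passed: the total of coculture 72 h replicate 4 (21.4 M, others 17.25 to 17.8) and the nuclear ribosomal RNA of coculture 24 h replicate 2 (4.07%, others 0.708 to 0.815) and coculture 72 h replicate 1 (2.24%, others 0.788 to 0.855).

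Interferon response genes were higher in coculture at 72 h, with a median log2 of 1.03. Within coculture at 24 h, with 2 libraries per lane, the list differed between the lanes by a median of 0.0742 (quartiles 0.023 to 0.166). This is far below the effect at 72 h, though the quartiles run over genes and do not measure the spread between libraries. Of the 2 lane 6 libraries, replicate 2 held 4.07% nuclear ribosomal RNA, so the lane difference also carries what sets that library apart. With that limit, the small lane difference argues against a lane effect of the same size at both times as the whole cause. A lane effect confined to 72 h was not tested. The mean share of nuclear ribosomal RNA differed by only -0.026 percentage points between the cultures at 72 h. Its predicted log2 of 8.48e-05 is thus near 0 at almost any slope. A difference in mean share is excluded as the cause, but the slope was not put to a test. At 24 h, where the label code parts the cultures as at 72 h, the median was 0.27 (0.272; quartiles -0.0407 to 0.493), which excludes a code effect of the same size at both times as the whole cause. RNA of leukocytes cannot be told apart, since only 2 markers of that list are measured.

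Cell cycle genes were higher in coculture at 72 h, with a median log2 of 0.97. Within coculture at 24 h, with 2 libraries per lane, the lanes differed by a median of -0.11 (-0.1055, quartiles over genes -0.153 to -0.0456) in the opposite direction. Nuclear ribosomal RNA predicts -0.000112. This is near 0 at almost any slope, because the mean share differed by only -0.026 percentage points between the cultures. With library sizes alone the median was 1.10 (1.099). At 24 h, where the label code parts the cultures in the same way, the median was -0.000449 (quartiles -0.0853 to 0.0872). Scaling and a difference in mean ribosomal RNA share are excluded as the whole cause, and a code effect only if of the same size at both times. The lane values also carry coculture 24 h replicate 2, with 4.07% nuclear ribosomal RNA. With that limit, they argue against a lane effect of the same size at both times, while one confined to 72 h was not tested. No biological explanation was tested.

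Cholesterol biosynthesis genes were lower in coculture in proliferation, with a median log2 of -0.54. With library sizes alone the median was -0.60 (-0.605), so scaling is excluded as the whole cause. Nuclear ribosomal RNA predicts 0.00143 (95% interval -0.006 to 0.00887). That slope comes from within the groups, where the share varied most in 4 libraries at 24 h and 72 h. In proliferation the share was 1.23 to 1.40% in monoculture and 0.742 to 1.07% in coculture. The slope thus argues against an effect like that within groups, but not against one that parts the cultures in proliferation. Lane and label code are the same in the 8 libraries. No biological explanation was tested, nor an effect of the insert itself, since the labels do not say whether monoculture wells held one.

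For each count of called genes only 1 split, the real one, gave as many genes, the lowest share that 35 or 40 splits can give. Chance in how these libraries fall into groups would thus give this in about 1 of 35 or 1 of 40 draws. The other splits of 2 groups mix the real groups, so a large difference between them becomes spread and few genes can be called. A batch that parts the groups would give the same result. The labels do not show that the spread between libraries is more than technical, so these splits do not address a chance difference between cultures. In fits to only the libraries compared, over 35 splits each, coculture against monoculture gave 7343, 2677 and 5568 genes in proliferation, at 24 h and at 72 h, and the highest other split 0. Over time the real splits gave 8148 and 5570 genes in monoculture and 5459 and 6178 in coculture, and the highest other 0. For the changes of the effect, over 40 splits each, the real ones gave 6156 (24 h less proliferation), 7409 (72 h less proliferation) and 2522 (72 h less 24 h), and the highest others 4852, 4508 and 0. The splits with 4852 and 4508 keep the real culture labels in proliferation.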

How the results depend on the processing

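Leaving out libraries or genes of nuclear ribosomal RNA and all alternatives for the correlation between times were chosen after seeing the data; the rest were planned. Of 1160 values for the 60 named results of coculture against monoculture none changed direction or its side of the threshold. The naming rule picks large called changes without overlap between the groups, so this was likely from the start. It says nothing of the smaller changes called. PDE4B at 72 h moved most, to 4.12 without the 4 libraries rich in ribosomal RNA. The 10 counts of called genes stayed within 1.5 times with DESeq2 (2740 to 8045), limma voom (2817 to 8184), other scaling factors (2791 to 8170), library sizes alone (2450 to 8271), a fit to only the libraries compared (2522 to 8148), the sample number as a block (2708 to 8127), a CPM filter (2829 to 8180), without ribosomal RNA genes (2837 to 8184) or without those 4 libraries (2710 to 8346). A stable count does not mean that the same genes were called. With library sizes alone, 4545 of 6277 calls at 72 h were among those of the main fit, against 5791 of 5856 with DESeq2. For the change of the effect from 24 h to 72 h, library sizes alone shared 1927 of 3411 calls. The comparison with no filter is void, as the filter removes 0 genes.

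Leaving out 1 library at a time gave 6417 to 6817, 2329 to 2627 and 5408 to 5858 genes for coculture against monoculture at the 3 times. The changes of the effect gave 5529 to 5906 (24 h less proliferation), 7074 to 7430 (72 h less proliferation) and 2398 to 2910 (72 h less 24 h). Over time monoculture gave 7775 to 7947 and 5986 to 6332, and coculture 4480 to 4807 and 5211 to 5401.

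Counts moved by over 1.5 times in these cases. A change of at least 2-fold, by its construction, left 77, 58 and 344 genes for coculture against monoculture, 161, 606 and 248 for the changes, 534 and 716 over time in monoculture, and 180 and 552 in coculture. An adjusted p under 0.01 left 1713 genes at 24 h and 1632 for the change from 24 h to 72 h. Lane 6 alone gave 1746 genes at 24 h, from fewer libraries. The lane covariate gave 3402 genes at 72 h, where it rests on 4 libraries, and moved the correlation of effects to 0.08 (0.0777) for proliferation and 24 h and 0.60 for 24 h and 72 h; the cause was not tested. With an estimated correlation 8 of 10, 6 of 6 and 12 of 15 lists lost their call at the 3 times. Data were also simulated with this depth and number of libraries, and with 1 spread per gene for all groups. Of the 1.5-fold changes in them, 87%, 93% and 85% were recovered at the 3 times. Only 200 genes were changed there, far fewer than were called in the data, so these shares need not hold for the data. Depth alone was not varied.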

Other observations

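The lane test for glycolysis genes was chosen after the result was seen. Fibroblast and fibro-adipogenic progenitor markers did not move as a group in coculture against monoculture (camera adjusted p = 0.868, 0.262 and 0.972 in proliferation, at 24 h and at 72 h). Of 24 measured, 8 rose and 6 fell in proliferation (4 and 10 with library sizes alone), 5 and 5 at 24 h (4 and 3 within lane 6 alone), and 5 and 7 at 72 h (10 and 4 with library sizes alone). PDGFRA fell slightly in proliferation (log2 -0.14 ± 0.0578) and rose at 24 h (0.47 ± 0.0583) and 72 h (1.38 ± 0.0582), and its effect changed by 0.91 ± 0.0822 between 24 h and 72 h. PRRX1 (0.61) and TCF7L2 (0.54) also rose at 72 h, while S100A4 (-0.77) and the ecto-nucleotidase NT5E (-0.62) fell.

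Adipocyte markers had 1 of 10 higher and 5 lower at 72 h, the fatty acid binding protein FABP4 (-1.05) and CIDEA (-0.57) lower and SCD (0.61) higher (adjusted p = 0.037, but adjusted p = 0.183 with an estimated correlation). Bone and cartilage markers fell in 4 of 5 cases at 72 h (2 with the lane covariate), SPP1 and SOX9 (-1.07) most (adjusted p = 0.00971, but adjusted p = 0.0962 with an estimated correlation). Notch pathway genes rose in 9 of 15 cases (5 with library sizes alone) and fell in 2 in proliferation, LFNG (0.51) highest, and at 72 h 3 rose and 7 fell (1 and 6 with the lane covariate), HES4 (-0.97) and HEYL (-0.94) lowest, where the median of -0.10 turns to 0.03 with library sizes alone (adjusted p = 0.0876 and 0.158). Of 15 atrophy and protein breakdown genes 3 rose and 6 fell in proliferation, 4 and 6 at 24 h (4 and 7 adjusted over the list alone, 1 and 4 within lane 6 alone), and 6 and 5 at 72 h (list adjusted p = 0.367, 0.0611 and 0.972), with KLF15 at -1.01 at 24 h and KLF9 at 1.44 and KLF15 at -1.23 at 72 h. Of 3 endothelial markers, ERG rose in proliferation (0.22; none adjusted over the list alone or with library sizes alone) and fell at 24 h (-0.39), and VWF rose at 72 h (0.80; list adjusted p = 0.868, 0.539 and 0.844). Of the leukocyte list 2 genes are measured, CD68 and FCER1G, and neither was called at any time over all genes, while adjusted over the list alone FCER1G fell at 24 h (-0.62).

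Over time, the mitochondrially encoded genes rose in 12 of 13 cases in monoculture over the first 24 h (adjusted p = 1.23e-05, but adjusted p = 0.291 with an estimated correlation) and in 13 of 13 in coculture (adjusted p = 1.62e-10, but adjusted p = 0.149 with an estimated correlation). From 24 h to 72 h glycolysis and hypoxia genes rose in 24 of 31 cases in coculture and 1 fell (adjusted p = 2.66e-10, but adjusted p = 0.122 with an estimated correlation), and in monoculture 18 rose and 4 fell (adjusted p = 0.000531, but adjusted p = 0.464 with an estimated correlation). Between 24 h and 72 h the coculture effect on growth factors fell for 15 of 40 genes and rose for 6, NOG (-1.54) and IGFBP3 (-1.30) lowest, but with library sizes alone for 8 and 8 (adjusted p = 0.00678, and adjusted p = 0.0411 with an estimated correlation).

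Glycolysis and hypoxia genes, with the lactate exporter SLC16A3 at the top, were higher in coculture at each time. In proliferation, where all libraries lie in lane 6, the list median was a log2 of 0.33, and within lane 6 at 24 h it was 0.36 (0.3589), which excludes the lane as the whole cause at these 2 times. At 72 h the lane covariate left a median of 0.54. The list lost its call with an estimated correlation at each time.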
